A study of Homo sapiens with 18 samples.

How the data were processed

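Total RNA of 18 plates of human cells was sequenced, 9 plates of the acute myeloid leukaemia line THP1 and 9 plates of its subclone B11, each line with 3 plates at 0, 1 and 10 ug/ml doxycycline for 5 days. Per the labels' protocols, RNA was prepared with an RNeasy kit and libraries with a standard Illumina protocol. Whether the libraries keep strand is not given in the sources used here, so reads of overlapping genes on opposite strands may have been summed.

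The deposited table holds 1 FPKM value (fragments per kilobase of transcript, scaled for depth) per gene and library, for 60658 Ensembl gene IDs. Per the submitters' processing notes, reads were aligned with HISAT2 to GRCh38 and the values were made with Cuffnorm. Versions, annotation release, filters and the scaling option of Cuffnorm are not given in the sources used here. The table's header names no unit, so FPKM was inferred from the tool named in those notes and from the values, which were not whole, never negative, and summed to between 1.01 and 1.20 M per library. Columns were matched to samples by the sample number in the titles, and no column was left unmatched. Symbols and coordinates came from GENCODE release 29 on GRCh38, which named 57047 of the IDs and left 3611 without a name.

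No read counts were used. Relative depth was recovered from ratios between libraries of the values of genes that stayed below 1 FPKM. It ranged from 0.847 to 1.22 times the mean, a ratio of 1.44 between the deepest and the shallowest library. Absolute depth was set from the smallest values of 403 genes with a single transcript, and came to an estimated 11.6 to 16.7 M fragments per library. The estimate was used to describe depth and to compute the counting noise given next, and did not enter the fit. Replicate libraries correlated at Pearson r of 0.938 to 0.958 across genes, and their variance was 16.0 to 30.7 times that of counting noise, so none was treated as a duplicate.

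Genes with at least 1 FPKM in at least 3 of the 18 libraries were kept, 17555 in all. Values were taken as log2(FPKM + 1), so that fold changes of low genes are understated. Means of the 6 groups were fitted in 1 model with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance moderation and 12 residual degrees of freedom. The 12 comparisons were the 3 dose contrasts in each line, the 3 contrasts between lines at equal dose, and the 3 differences of the dose response between lines (interactions). P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called changed at an adjusted p under 0.05. All adjusted p-values of genes are from this limma fit.

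Before the data were examined, 28 gene lists were fixed. Each was tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over all 336 tests. Of these, 169 were called, and 71 of the 169 were also called with an estimated correlation. A list's call that was lost with the estimated correlation is given with that p beside it. Counts of list members are given over all genes tested and adjusted over the list alone. Plain medians are over the log2 changes of the members.

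Genes to be named were set by a rule written before the data were examined. NRAS was named in every comparison. In 6 main comparisons, the 8 rising and 8 falling genes with the largest fitted change were named among those that passed, reached a mean of 5 FPKM in the higher group and had all 3 libraries of one group above all 3 of the other. For the interaction, the highest of the 4 group means had to reach 5 FPKM and separation of libraries was not required. Names of clones, small RNAs and numbered pseudogenes were left out. From each list described in a comparison, up to 4 members that passed with the smallest p were eligible, or the 1 to 2 most abundant where none passed.

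On simulated data for the comparison of B11 at 10 and 0 ug/ml, with 200 changed genes among 17555, the fit called 20.6% of genes changed by 0.5 on the log2 scale, 57.5% of those changed by 1 and 81.5% of those changed by 2. The share of false calls was 6.68%, above the adjusted p threshold of 0.05. The real comparison called 7520 genes, many more than were changed here, so these shares do not carry over to it. Alternatives covered the pseudocount, the filter, the scaling (median of ratios and TPM), the moderation, the libraries in the fit, the replicate letter as a block, and each library left out in turn. A restriction to named protein-coding genes of at least 300 exonic bases and a fit without 2 libraries, which leaves 1 library in that group, were chosen after seeing the data. The planned count-based alternative was not run because the table holds FPKM. The labels give no batch. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.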

Results

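THP1 is a human acute myeloid leukaemia line of monocytic type that, per the labels, carries a heterozygous NRAS G12D mutation. NRAS encodes a small GTPase that drives the MAPK cascade. B11 is a subclone made, per the labels, from THP1 with a doxycycline-inducible, CRISPR-resistant NRAS G12V and GFP, in which Cas9 and dual guide RNAs were aimed around the start codon of NRAS. THP1 given the same doses was used here to measure the response to doxycycline in the parent line. Each of the 6 groups held 3 plates from one grown-out culture per line, and B11 is 1 clone, so p-values measure only the spread between plates. Values are mean FPKM ± SD of 3 libraries, and changes are differences of log2(FPKM + 1) with their standard error (SE). Estimated depth was 11.6 to 16.7 M fragments per library. The groups, comparisons, gene lists and the rule for naming genes were set before the data were examined.

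The first 2 principal components held 25.3% and 15.4% of the variance. Untreated B11 lay at 77.2 to 77.8 on the first component, treated B11 at 14.4 to 21.01 and all THP1 libraries at -41.6 to -31.6. On the second component treated B11 lay at -38.1 to -35.5 at 1 ug/ml and at -54.8 to -48.8 at 10 ug/ml.

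**Figure D1:**
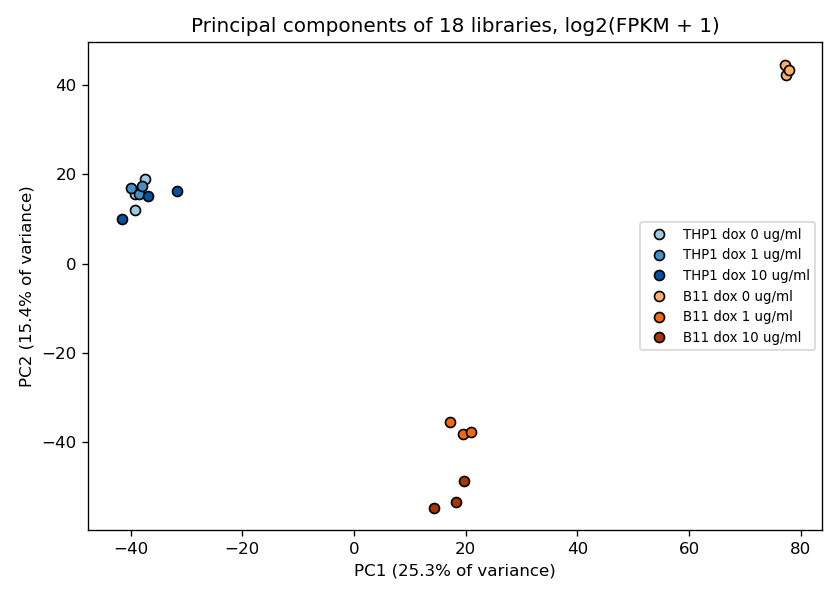
Scores of the 18 libraries on the first 2 principal components of log2(FPKM + 1), with 1 point per library coloured by line and doxycycline dose. The 3 untreated B11 libraries lie at 77.2 to 77.8 on the first component, treated B11 at 14.4 to 21.01 and THP1 at -41.6 to -31.6.

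NRAS (chromosome 1, 114704469 to 114716894 on the minus strand of GRCh38) was at 20.95 ± 1.09 FPKM in untreated B11, 23.8 ± 0.579 at 1 ug/ml and 28.0 ± 0.219 at 10 ug/ml. In THP1 NRAS was at 23.3 ± 0.349, 23.4 ± 1.97 and 24.3 ± 0.505 FPKM. The rise of NRAS in B11 from 0 to 10 ug/ml was 0.40 (SE 0.07, adjusted p = 0.00028), and it exceeded the change in THP1 by 0.35 (SE 0.10, adjusted p = 0.016). The difference in B11 was 0.18 (SE 0.07, adjusted p = 0.061) from 0 to 1 ug/ml and 0.22 (SE 0.07, adjusted p = 0.049) from 1 to 10 ug/ml, and the latter passed only without a filter or at a mean of at least 5 FPKM and was lost in the other 16 alternatives, among them TPM scaling (adjusted p = 0.097) and each library left out. NRAS in B11 differed from THP1 by -0.15 (SE 0.07, adjusted p = 0.099) at 0 ug/ml, 0.03 (SE 0.07, adjusted p = 0.83) at 1 ug/ml and 0.20 (SE 0.07, adjusted p = 0.042) at 10 ug/ml, and the last was lost in 13 of 17 alternatives, among them TPM (adjusted p = 0.273) and each library left out. In THP1 the NRAS difference was 0.00 (SE 0.07, adjusted p = 1) at 1 and 0.06 (SE 0.07, adjusted p = 0.86) at 10 against 0 ug/ml, and 0.05 (SE 0.07, adjusted p = 0.88) at 10 against 1 ug/ml. The NRAS response of B11 minus that of THP1 was 0.17 (SE 0.10, adjusted p = 0.23) at 1 ug/ml and 0.17 (SE 0.10, adjusted p = 0.39) from 1 to 10 ug/ml. The table gives 1 value for the gene, in which transcripts of the transgene and of the edited gene are not separable.

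In B11 at 10 against 0 ug/ml, proliferation genes and genes downstream of MAPK signalling rose, and genes of mature monocytes fell. CCNA2, a cyclin of S and G2 phase, rose from 3.39 ± 0.184 to 32.6 ± 0.838 FPKM, and RRM2, a subunit of ribonucleotide reductase, changed by 3.73 (SE 0.11). DUSP6, a phosphatase that inactivates ERK, changed by 3.04 (SE 0.14) from 1.67 ± 0.292 FPKM, and EGR1, an immediate early transcription factor, rose from 1.34 ± 0.0544 to 49.0 ± 3.37. Of 40 cell cycle genes, 40 rose and none fell (the same adjusted over the list alone, median 2.38, camera, adjusted p = 1.41e-35). Of 27 genes of MAPK output and feedback, 23 rose and none fell (25 higher and 0 lower adjusted over the list alone, median 1.22, camera, adjusted p = 7.68e-12). Genes that encode the RAS-RAF-MEK-ERK components were not called as a list, and of 26 genes, 7 fell and 6 rose (7 higher and 7 lower adjusted over the list alone, median 0.20, camera, adjusted p = 0.866).

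Of 43 genes of monocyte and macrophage differentiation, 25 fell and 4 rose (the same adjusted over the list alone, median -0.54, camera, adjusted p = 1.15e-08). The subunits of calprotectin fell, S100A8 from 113 ± 24.0 to 2.78 ± 0.734 FPKM and S100A9 from 197 ± 34.4 to 8.71 ± 2.52. CSF1R, the receptor of macrophage colony-stimulating factor, changed by -3.54 (SE 0.10), and LYZ, which encodes lysozyme, by -3.23 (SE 0.11). Of 18 myeloblast and granulocyte genes, 12 fell and 1 rose (1 higher and 14 lower adjusted over the list alone, median -0.77, camera, adjusted p = 2.12e-07), among them the granule proteins AZU1 at -1.39 (SE 0.05) and ELANE at -1.14 (SE 0.06). Of 21 targets of PI3K, AKT and FOXO, 11 fell and 3 rose (3 higher and 12 lower adjusted over the list alone, median -0.57, camera, adjusted p = 0.00305), with TXNIP, which restrains glucose uptake, at -2.67 (SE 0.09).

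Biosynthetic and stress genes also rose in B11 at 10 against 0 ug/ml. SRM, the spermidine synthase, changed by 1.39 (SE 0.07) and HSPA5, the main chaperone of the endoplasmic reticulum, by 1.37 (SE 0.06). Of 30 MYC targets and ribosome biogenesis genes, 25 rose and none fell (the same adjusted over the list alone, median 0.82, camera, adjusted p = 3.92e-13). Of 28 unfolded protein response and heat shock genes, 22 rose and none fell (the same adjusted over the list alone, median 1.09, camera, adjusted p = 2.29e-14). Of 30 genes of the mitochondrial ribosome and translation, 22 rose and none fell (the same adjusted over the list alone, median 0.71, camera, adjusted p = 4.39e-09). Of 25 cholesterol synthesis genes, 21 rose and none fell (the same adjusted over the list alone, median 1.10, camera, adjusted p = 2.6e-11, but adjusted p = 0.0519 with an estimated correlation), with SQLE, an early enzyme of the sterol branch, at 1.53 (SE 0.10). Of 16 fatty acid synthesis and LXR genes, 10 rose and 3 fell (the same adjusted over the list alone, median 0.70, camera, adjusted p = 0.0035, but adjusted p = 0.067 with an estimated correlation), with the fatty acid synthase FASN at 2.19 (SE 0.11).

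Of 38 genes of the ATF4 integrated stress response in B11 at 10 against 0 ug/ml, 33 rose and none fell (the same adjusted over the list alone, median 1.42, camera, adjusted p = 8.1e-13, but adjusted p = 0.148 with an estimated correlation), with TRIB3 at 2.55 (SE 0.15) and MTHFD2 at 2.15 (SE 0.14). Of 31 glycolysis and hypoxia genes, 23 rose and 1 fell (the same adjusted over the list alone, median 0.83, camera, adjusted p = 5.71e-08, but adjusted p = 0.156 with an estimated correlation). Of 41 nuclear genes of oxidative phosphorylation, 31 rose and 2 fell (the same adjusted over the list alone, median 0.46, camera, adjusted p = 2.48e-09, but adjusted p = 0.134 with an estimated correlation). Of 15 mitochondrially encoded genes, 13 fell and none rose (0 higher and 14 lower adjusted over the list alone, median -0.72, camera, adjusted p = 3.34e-07, but adjusted p = 0.25 with an estimated correlation), and the mitochondrial share of the FPKM sum was 4.82 ± 0.665% in untreated B11 and 3.15 ± 0.619% at 10 ug/ml. Of 20 NRF2 genes, 11 rose and 4 fell (the same adjusted over the list alone, median 0.31, camera, adjusted p = 0.0143, but adjusted p = 0.219 with an estimated correlation), with PRDX1 at 1.18 (SE 0.07). Of 10 histone genes, 7 fell and 1 rose (the same adjusted over the list alone, median -0.99, camera, adjusted p = 0.017, but adjusted p = 0.129 with an estimated correlation).

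Among genes that met the rule for naming by size, the largest rises in B11 at 10 against 0 ug/ml were in AKR1C2 and AKR1C3. These are aldo-keto reductases of steroid metabolism on chromosome 10 (4987400 to 5018031 and 5035354 to 5107686). AKR1C2 rose from 0.367 ± 0.348 to 631 ± 12.3 FPKM, a change of 8.88 (SE 0.28, adjusted p = 4.8e-12), and AKR1C3 changed by 5.43 (SE 0.39). AKR1C1 was listed at 0 in all 3 untreated libraries and at 46.5 ± 28.0 FPKM with doxycycline. These 3 genes are close copies, so the split of reads between them is uncertain. TERT, the catalytic subunit of telomerase, rose from 0.682 ± 0.409 to 29.9 ± 2.65 FPKM. RAB3IL1 changed by 4.36 (SE 0.66), GNAI1 by 3.98 (SE 0.29) and CEP97 by 4.09 (SE 0.93), where CEP97 was at 90.3 ± 83.4 FPKM in treated libraries and lost its call when the fit held only the 2 groups compared (adjusted p = 0.0733). CFP, which encodes properdin of the complement system, fell from 261 ± 39.3 to 11.02 ± 2.65 FPKM. GLIPR1 fell by 4.54 (SE 0.14), PTGDS by 4.52 (SE 0.20), CD36 by 4.27 (SE 0.20), NFE2 by 3.96 (SE 0.09) and OLFML3 by 3.72 (SE 0.14). GLIPR1 and CD36 overlap KRR1 and GNAT3 on the other strand, and AKR1C2, AKR1C3, GNAI1, NFE2 and OLFML3 overlap other annotated genes there. In total 7520 genes passed, 3784 higher and 3736 lower, and 1378 and 1402 of these changed at least 2-fold. The split was 3685 higher and 3856 lower with the median of ratios, and 4192 higher and 3238 lower with TPM.

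**Figure D2:**
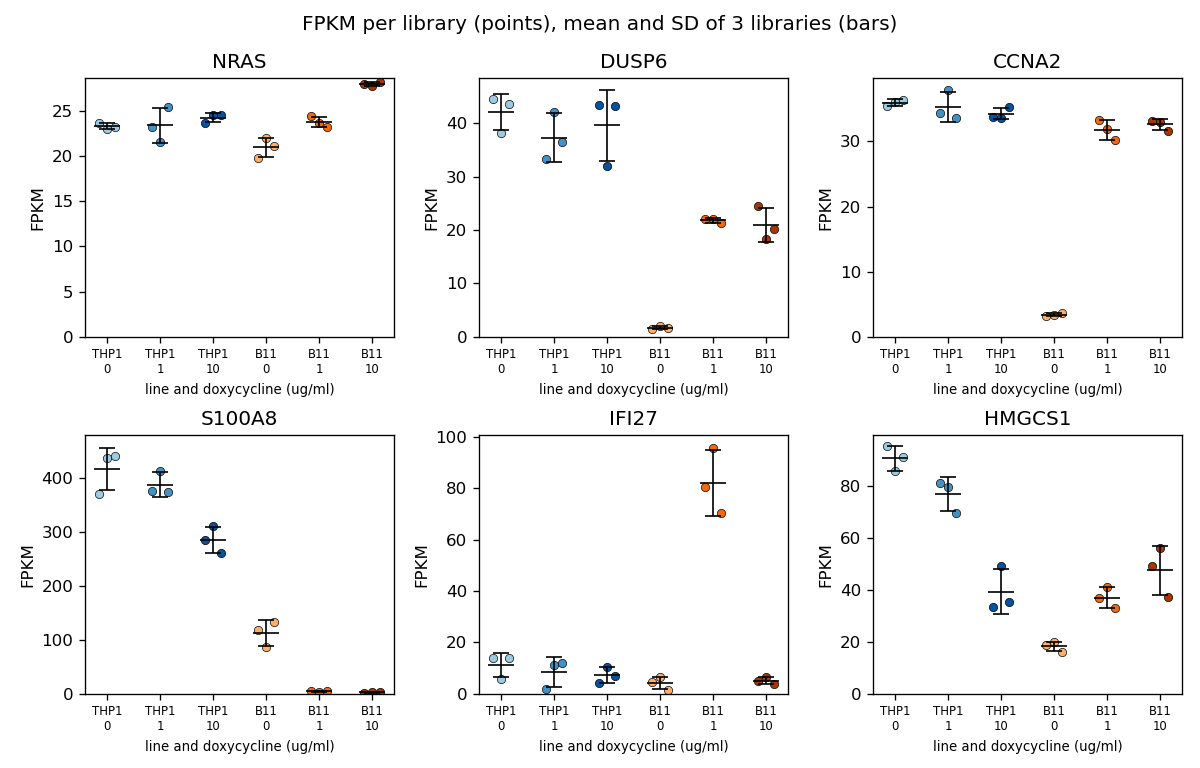
FPKM of NRAS, DUSP6, CCNA2, S100A8, IFI27 and HMGCS1 in each library (points), with the mean and SD of 3 libraries (bars), by line and doxycycline dose in ug/ml. S100A8 is at 113 ± 24.0 FPKM in untreated B11 and 2.78 ± 0.734 at 10 ug/ml, and IFI27 is at 82.1 ± 12.9 in B11 at 1 ug/ml.

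In B11 at 1 against 0 ug/ml, proliferation genes rose along with interferon genes. ISG15, a ubiquitin-like modifier, rose from 38.7 ± 2.68 to 145 ± 14.7 FPKM and IFI6 from 66.5 ± 7.41 to 221 ± 15.3, and CCNA2 changed by 2.90 (SE 0.07). Of 38 interferon response genes, 30 rose and 1 fell (31 higher and 2 lower adjusted over the list alone, median 0.94, camera, adjusted p = 1.67e-09). Of 40 cell cycle genes, 40 rose and none fell (the same adjusted over the list alone, camera, adjusted p = 2.64e-41). Of 27 MAPK output genes, 22 rose and 1 fell (the same adjusted over the list alone, median 1.19, camera, adjusted p = 1.49e-10), with DUSP6 at 3.10 (SE 0.14). Of 30 MYC targets, 26 rose and none fell (the same adjusted over the list alone, median 0.88, camera, adjusted p = 5.93e-15), and of 28 unfolded protein response genes, 24 rose and none fell (the same adjusted over the list alone, median 0.88, camera, adjusted p = 2.45e-15). Of 38 ATF4 genes, 37 rose and none fell (the same adjusted over the list alone, median 1.98, camera, adjusted p = 4.39e-21, but adjusted p = 0.067 with an estimated correlation), with TRIB3 at 3.95 (SE 0.15). Of 43 monocyte genes, 22 fell and 8 rose (10 higher and 23 lower adjusted over the list alone, median -0.58, camera, adjusted p = 0.000233, but adjusted p = 0.0836 with an estimated correlation), with S100A8 at -4.40 (SE 0.19). In total 6516 genes passed, 3472 higher and 3044 lower, and 3833 were higher and 2521 lower with TPM. An unnamed ID was at 1.95e-37 FPKM or less in all libraries except B and C of B11 at 1 ug/ml. These 2 libraries held it at 76850 and 42500 FPKM, 6.51% and 3.76% of the FPKM sum by which TPM divides. The count without both was 4053, from a fit with 1 library left at that dose, so a loss of replicates cannot be told from an effect of those libraries.

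In B11 at 10 against 1 ug/ml, interferon and monocyte genes fell. IFI27, on chromosome 14 (94104836 to 94116698), fell from 82.1 ± 12.9 to 5.13 ± 1.40 FPKM, and OAS1, a sensor of double-stranded RNA, from 46.2 ± 4.75 to 5.74 ± 0.807. IFI6 changed by -2.46 (SE 0.07) and ISG15 by -1.90 (SE 0.10). Of 38 interferon response genes, 28 fell and 1 rose (1 higher and 31 lower adjusted over the list alone, median -1.20, camera, adjusted p = 9.77e-26). Of 43 monocyte genes, 22 fell and 2 rose (4 higher and 27 lower adjusted over the list alone, median -0.55, camera, adjusted p = 1.09e-09), with CSF1R at -1.56 (SE 0.10) and CD14, a receptor for lipopolysaccharide, at -1.84 (SE 0.15). Of 27 MAPK output genes, 7 rose and 1 fell (10 higher and 1 lower adjusted over the list alone, median 0.23, camera, adjusted p = 0.00132), with EGR1 at 1.19 (SE 0.12) and CCND1, which encodes cyclin D1, at 1.42 (SE 0.26). Of 38 ATF4 genes, 16 fell and none rose (0 higher and 23 lower adjusted over the list alone, median -0.56, camera, adjusted p = 2.35e-09, but adjusted p = 0.21 with an estimated correlation), with SESN2 at -1.32 (SE 0.13). Of 25 cholesterol synthesis genes, 10 rose and 1 fell (12 higher and 1 lower adjusted over the list alone, median 0.34, camera, adjusted p = 9.11e-06, but adjusted p = 0.164 with an estimated correlation), with MSMO1 at 1.36 (SE 0.23). The unnamed ID stood at 76850 and 42500 FPKM in libraries B and C of B11 at 1 ug/ml.

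Among single genes in B11 at 10 against 1 ug/ml, PPP1R27 rose from 586 ± 16.5 to 2235 ± 46.8 FPKM, and SERPINB2, an inhibitor of plasminogen activators, from 19.9 ± 0.734 to 88.9 ± 1.75. AKR1C2 changed by 2.19 (SE 0.28), AKR1C1 by 2.05 (SE 0.30), CACNB1 by 1.83 (SE 0.35), GNAI1 by 1.76 (SE 0.29), PLD1 by 1.77 (SE 0.40) and RASA4B by 2.38 (SE 0.62, adjusted p = 0.021). TRIM22 fell by 3.18 (SE 0.31), SIGLEC1 by 2.87 (SE 0.17), G0S2 by 2.84 (SE 0.25), MPEG1 by 2.83 (SE 0.14), GLIPR1 by 2.77 (SE 0.14) and CD36 by 2.70 (SE 0.20). TRIM22 and MPEG1 overlap TRIM5 and DTX4 on the other strand, and OAS1, CACNB1, G0S2, AKR1C2, GNAI1, GLIPR1 and CD36 overlap other annotated genes there. On the same strand, SERPINB2 overlaps SERPINB10, and RASA4B and TRIM22 overlap other annotated genes. In total 2249 genes passed, 999 higher and 1250 lower. The count was 601 without libraries B and C at 1 ug/ml, which left 1 library at that dose, and PLD1 and RASA4B had adjusted p = 0.187 and 0.233 in that fit. It was 1478 without library C at 1 ug/ml and 1475 without library C at 10 ug/ml. RASA4B lost its call in 6 alternatives, 5 of them with 1 library left out.

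In THP1 at 10 against 0 ug/ml, cholesterol synthesis and inflammatory genes fell. HMGCS1, which feeds the mevalonate pathway, fell from 90.8 ± 4.80 to 39.3 ± 8.62 FPKM, and FDPS, a later enzyme of that pathway, from 1000 ± 24.6 to 534 ± 35.0. NFKBIA, an inhibitor of NF-kB, changed by -0.94 (SE 0.14), and EBI3, a cytokine subunit, by -2.37 (SE 0.41). Of 25 cholesterol synthesis genes, 15 fell and none rose (0 higher and 22 lower adjusted over the list alone, median -0.68, camera, adjusted p = 2.48e-36). Of 30 inflammatory and NF-kB genes, 11 fell and none rose (0 higher and 22 lower adjusted over the list alone, median -0.65, camera, adjusted p = 8.81e-24). Of 16 immediate early genes, 8 fell and none rose (0 higher and 12 lower adjusted over the list alone, median -0.52, camera, adjusted p = 7.39e-17), with BTG2 at -1.01 (SE 0.09). Of 31 glycolysis and hypoxia genes, 9 fell and none rose (0 higher and 21 lower adjusted over the list alone, median -0.43, camera, adjusted p = 4.79e-21). Of 43 monocyte genes, 7 fell and none rose (1 higher and 18 lower adjusted over the list alone, median -0.36, camera, adjusted p = 6.84e-18), with FCGR2B at -1.68 (SE 0.18). Of 38 ATF4 genes, 2 rose and 1 fell (8 higher and 1 lower adjusted over the list alone, median 0.34, camera, adjusted p = 2.6e-11, but adjusted p = 0.168 with an estimated correlation), with ASNS, which makes asparagine, at 0.91 (SE 0.20). Of 40 cell cycle genes, none rose or fell (the same adjusted over the list alone, median -0.08, camera, adjusted p = 0.00295, but adjusted p = 0.19 with an estimated correlation).

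Further lists were called lower in THP1 at 10 against 0 ug/ml, although few of their members passed. Of 27 MAPK output genes, 1 fell and none rose (0 higher and 5 lower adjusted over the list alone, median -0.12, camera, adjusted p = 0.00046). Of 38 interferon genes, 2 fell and none rose (0 higher and 3 lower adjusted over the list alone, median -0.21, camera, adjusted p = 5.45e-05). Of 21 targets of PI3K, AKT and FOXO, 1 fell and none rose (0 higher and 3 lower adjusted over the list alone, median -0.27, camera, adjusted p = 6.29e-06). Of 16 fatty acid synthesis and LXR genes, 3 fell and none rose (0 higher and 6 lower adjusted over the list alone, median -0.19, camera, adjusted p = 7.6e-07), with FADS2 at -0.93 (SE 0.11). Of 5 measured marker genes of T and NK cells, none rose or fell (0 higher and 2 lower adjusted over the list alone, median -0.71, camera, adjusted p = 0.00354).

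Among single genes in THP1 at 10 against 0 ug/ml, NKD2, a Wnt antagonist, rose from 10.4 ± 1.01 to 19.5 ± 1.61 FPKM and CBS, an enzyme of homocysteine metabolism, changed by 1.57 (SE 0.32). GIPC1 changed by 0.74 (SE 0.14), ZNF195 by 0.64 (SE 0.14), GAS5 by 0.58 (SE 0.11), TMEM131L by 0.57 (SE 0.12) and MLST8 by 0.46 (SE 0.08). TBC1D30 fell by 2.05 (SE 0.29), SLC6A8 by 1.97 (SE 0.35), ALDOC by 1.94 (SE 0.40), CCL3 by 1.92 (SE 0.29), FCGR2C by 1.90 (SE 0.22), HSPA7 by 1.79 (SE 0.18) and IGFBP3 by 1.76 (SE 0.20). FCGR2C, FCGR2B and HSPA7 have close copies, and FCGR2C overlaps another annotated gene on the same strand, so their values are uncertain. The falls of FCGR2B and FCGR2C may therefore not be separate. ASNS, GIPC1, ZNF195, GAS5, MLST8, TBC1D30, SLC6A8, ALDOC and CCL3 overlap annotated genes on the other strand, so their values are uncertain too. In total 179 genes passed, 17 higher and 162 lower, and 1835 had an unadjusted p under 0.05. Of the 16 genes chosen by size, 15 lost their call in at least 1 alternative, and FCGR2C kept it in the 15 alternatives in which it was tested. ASNS lost its call in 11 alternatives, CBS and ZNF195 in 10, GAS5 and TMEM131L in 8, ALDOC in 7, GIPC1, MLST8 and SLC6A8 in 4, EBI3 in 2, and NKD2, TBC1D30, CCL3, HSPA7 and IGFBP3 in 1. The count was 46 with only the 2 groups in the fit, 105, 67 and 69 without library A, B or C at 0 ug/ml, and 94 and 104 without library A or C at 10 ug/ml.

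In THP1 at 1 against 0 ug/ml, 2 genes passed, IGFBP3 at -1.68 (SE 0.20, adjusted p = 0.0081) and NKD2 at 0.71 (SE 0.10, adjusted p = 0.039), both named after their values were seen. Of 30 inflammatory genes, none rose or fell (0 higher and 17 lower adjusted over the list alone, median -0.46, camera, adjusted p = 2.49e-22), and of 16 immediate early genes, none rose or fell (0 higher and 9 lower adjusted over the list alone, median -0.32, camera, adjusted p = 2.25e-13). The split was 1 higher and 1 lower, and 0 higher and 1 lower with TPM or median of ratios scaling, and 958 genes had an unadjusted p under 0.05. Without library A, B or C at 0 ug/ml the count was 4, 0 and 0, and without library B at 1 ug/ml it was 0. In THP1 at 10 against 1 ug/ml, 52 genes passed, 9 higher and 43 lower. FDPS changed by -0.75 (SE 0.09) and the desaturase FADS2 by -0.92 (SE 0.11). Of 25 cholesterol synthesis genes, 9 fell and none rose (0 higher and 24 lower adjusted over the list alone, median -0.59, camera, adjusted p = 1.54e-33). Without library A, B or C the count was 17, 15 and 21 at 1 ug/ml and 20, 16 and 13 at 10 ug/ml.

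In untreated B11 against untreated THP1, proliferation, MAPK output and sterol genes were lower in B11. CCNA2 was at 3.39 ± 0.184 against 36.0 ± 0.524 FPKM, DUSP6 at 1.67 ± 0.292 against 42.1 ± 3.45, and RRM2 at 4.95 ± 1.32 against 133 ± 7.21. Of 40 cell cycle genes, 40 were lower and none were higher (the same adjusted over the list alone, median -2.69, camera, adjusted p = 1.13e-34). Of 27 MAPK output genes, 21 were lower and none were higher (the same adjusted over the list alone, median -1.17, camera, adjusted p = 4.72e-08), with MYC at -0.97 (SE 0.06). Of 25 cholesterol synthesis genes, 24 were lower and none were higher (the same adjusted over the list alone, median -1.63, camera, adjusted p = 2.29e-14), with SQLE at -2.72 (SE 0.10). Of 30 MYC targets, 24 were lower and 1 were higher (1 higher and 25 lower adjusted over the list alone, median -0.99, camera, adjusted p = 1.81e-12), and of 28 unfolded protein response genes, 20 were lower and 3 were higher (the same adjusted over the list alone, median -0.83, camera, adjusted p = 2.04e-09). Monocyte genes were not called as a list, and of 43 genes, 20 were lower and 13 were higher (the same adjusted over the list alone, median -0.29, camera, adjusted p = 0.193), with the lysosomal protein CD68 at 2.17 (SE 0.08). Of 18 myeloblast and granulocyte genes, 8 were higher and 2 were lower (9 higher and 2 lower adjusted over the list alone, median 0.25, camera, adjusted p = 0.00286, but adjusted p = 0.134 with an estimated correlation), with ELANE at 1.76 (SE 0.06). Of 15 mitochondrially encoded genes, 11 were higher and none were lower (12 higher and 0 lower adjusted over the list alone, median 0.48, camera, adjusted p = 7.93e-05, but adjusted p = 0.366 with an estimated correlation), where the mitochondrial share was 4.82% in B11 and 3.44% in THP1.

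NCAM1, a neural cell adhesion molecule (chromosome 11, 112961247 to 113278436), stood furthest above THP1 in untreated B11 among genes that met the rule for naming by size. It was at 154 ± 12.2 against 1.42 ± 0.485 FPKM. LTC4S, which makes leukotriene C4, was at 316 ± 18.5 against 29.8 ± 0.623 FPKM. SPP1, which encodes the secreted protein osteopontin, was at 1.83 ± 2.64 against 141 ± 20.3 FPKM, and MMP9, a secreted protease, at 0.213 ± 0.142 against 31.5 ± 1.99. GIPR differed by 3.95 (SE 0.79), ADIRF by 3.92 (SE 0.59), MS4A4E by 3.69 (SE 0.27), COL4A5 by 3.67 (SE 0.26), CLDN7 by 3.34 (SE 0.25) and CSN1S1 by 3.32 (SE 0.81). HSD11B1, which activates cortisone, differed by -5.27 (SE 0.18), C12orf75 by -4.54 (SE 0.42), GAL by -4.54 (SE 0.21) and TMEM176B by -4.43 (SE 0.13), and PNCK was listed at 0 in all 3 B11 libraries. NCAM1, ADIRF, MS4A4E, COL4A5, CLDN7, PNCK, HSD11B1, MMP9, C12orf75 and TMEM176B overlap other annotated genes on the opposite strand, and GIPR overlaps MIR642A on the same strand. In total 8269 genes passed, 4122 higher and 4147 lower in B11, and 3313 were higher and 4903 lower with TPM.

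In B11 against THP1 at 1 ug/ml, interferon genes were higher and monocyte genes lower in B11. ISG15 differed by 2.34 (SE 0.10), and S100A9 was at 14.6 ± 2.18 against 814 ± 55.2 FPKM. Of 38 interferon genes, 27 were higher and 1 were lower (30 higher and 1 lower adjusted over the list alone, median 1.02, camera, adjusted p = 7.03e-14). Of 43 monocyte genes, 27 were lower and 4 were higher (5 higher and 27 lower adjusted over the list alone, median -0.51, camera, adjusted p = 1.86e-08). Of 38 ATF4 genes, 36 were higher and none were lower (the same adjusted over the list alone, median 1.35, camera, adjusted p = 6.25e-21, but adjusted p = 0.067 with an estimated correlation), with ASNS at 2.81 (SE 0.20). In total 5231 genes passed, 2639 higher and 2592 lower in B11. With TPM the balance turned to 2336 higher and 2905 lower, and with the median of ratios it was 2608 higher and 2655 lower. TPM divides by a sum that includes the unnamed ID, which made up 6.51% and 3.76% of it in B11 libraries B and C. How much of the turn with TPM came from that ID was not tested. Without libraries B and C of B11 at 1 ug/ml, which held the unnamed ID at 76850 and 42500 FPKM, 2687 passed in a fit with 1 library left at that dose.

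In B11 against THP1 at 10 ug/ml, monocyte genes were lower and MAPK output genes higher in B11. S100A8 was at 2.78 ± 0.734 against 286 ± 24.7 FPKM, S100A9 at 8.71 ± 2.52 against 607 ± 6.74, and EGR1 at 49.0 ± 3.37 against 3.29 ± 0.727. Of 43 monocyte genes, 27 were lower and 4 were higher (4 higher and 28 lower adjusted over the list alone, median -0.84, camera, adjusted p = 1.04e-10). Of 27 MAPK output genes, 13 were higher and 3 were lower (the same adjusted over the list alone, median 0.47, camera, adjusted p = 0.00127). Of 40 cell cycle genes, 18 were lower and 6 were higher (7 higher and 21 lower adjusted over the list alone, median -0.30, camera, adjusted p = 0.00664, but adjusted p = 0.218 with an estimated correlation). AKR1C2 differed by 7.69 (SE 0.28), NCAM1 by 6.45 (SE 0.26), AKR1C3 by 5.29 (SE 0.39), AKR1C1 by 5.02 (SE 0.30), PPP1R27 by 3.49 (SE 0.08), FCER2, the low-affinity receptor for IgE, by 3.68 (SE 0.19) and the Notch ligand DLL1 by 3.24 (SE 0.17). SPP1 differed by -5.10 (SE 0.53), HSD11B1 by -4.53 (SE 0.18), PLEKHO1 by -4.34 (SE 0.23), LSP1 by -4.14 (SE 0.24) and CEACAM6 by -4.03 (SE 0.11), and TMEM176B was listed at 0 in all 3 B11 libraries. AKR1C2, AKR1C3, NCAM1, DLL1, HSD11B1, LSP1, CEACAM6 and TMEM176B overlap annotated genes on the opposite strand. In total 5691 genes passed, 2882 higher and 2809 lower in B11. The balance turned to 2487 higher and 3336 lower with TPM, and to 2755 higher and 3023 lower with the median of ratios.

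The interaction at 10 ug/ml gives the response of B11 minus that of THP1. INSIG1, a sterol-regulated brake on cholesterol synthesis, went from 34.3 ± 2.64 to 142 ± 25.9 FPKM in B11 and from 164 ± 8.54 to 80.4 ± 8.50 in THP1, a difference of 3.02 (SE 0.15, adjusted p = 2.6e-09). Of 40 cell cycle genes, 40 were higher and none were lower (the same adjusted over the list alone, median 2.52, camera, adjusted p = 2.64e-41). Of 27 MAPK output genes, 25 were higher and none were lower (the same adjusted over the list alone, median 1.59, camera, adjusted p = 1.91e-14). Of 25 cholesterol synthesis genes, 24 were higher and none were lower (the same adjusted over the list alone, median 1.83, camera, adjusted p = 5.53e-19). The difference was 8.20 (SE 0.39) for AKR1C2, 5.20 (SE 0.56) for AKR1C3, 5.35 (SE 0.94) for RAB3IL1, 4.94 (SE 0.16) for EGR1, 4.22 (SE 1.05) for MPP6, 4.08 (SE 0.34) for INAVA and 4.02 (SE 0.57) for ALDOC, and AKR1C1 was listed at 0 in untreated B11. It was -4.37 (SE 0.27) for S100A8, -3.98 (SE 0.28) for PTGDS, -3.84 (SE 0.28) for CD36, -3.81 (SE 0.24) for S100A9, -3.78 (SE 0.19) for GLIPR1, -3.73 (SE 0.20) for OLFML3, -3.51 (SE 0.19) for CFP and -3.41 (SE 0.12) for NFE2. MPP6 and ALDOC overlap annotated genes on the opposite strand, as do AKR1C2, AKR1C3, CD36, GLIPR1, OLFML3 and NFE2. In total 5230 genes passed, 2812 higher and 2418 lower in B11, and 3064 were higher and 2083 lower with TPM.

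In the interaction at 1 ug/ml, 4544 genes passed, 2509 higher and 2035 lower in B11, and 2860 were higher and 1643 lower with TPM. The TPM sum of B11 libraries B and C at 1 ug/ml includes the unnamed ID. Of 38 interferon genes, 25 were higher and 1 were lower (28 higher and 1 lower adjusted over the list alone, median 0.98, camera, adjusted p = 4.33e-11). In the interaction of 10 against 1 ug/ml, 814 genes passed, 395 higher and 419 lower in B11, with IFI6 at -2.43 (SE 0.10). Of 38 interferon genes, 20 were lower and none were higher (1 higher and 26 lower adjusted over the list alone, median -1.07, camera, adjusted p = 2.55e-23). The count of 814 became 495 without B11 library C at 1 ug/ml and 230 without libraries B and C, which held the unnamed ID at 76850 and 42500 FPKM and left 1 library at that dose. With a mean of at least 5 FPKM the split was 427 higher and 391 lower.

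**Figure D3:**
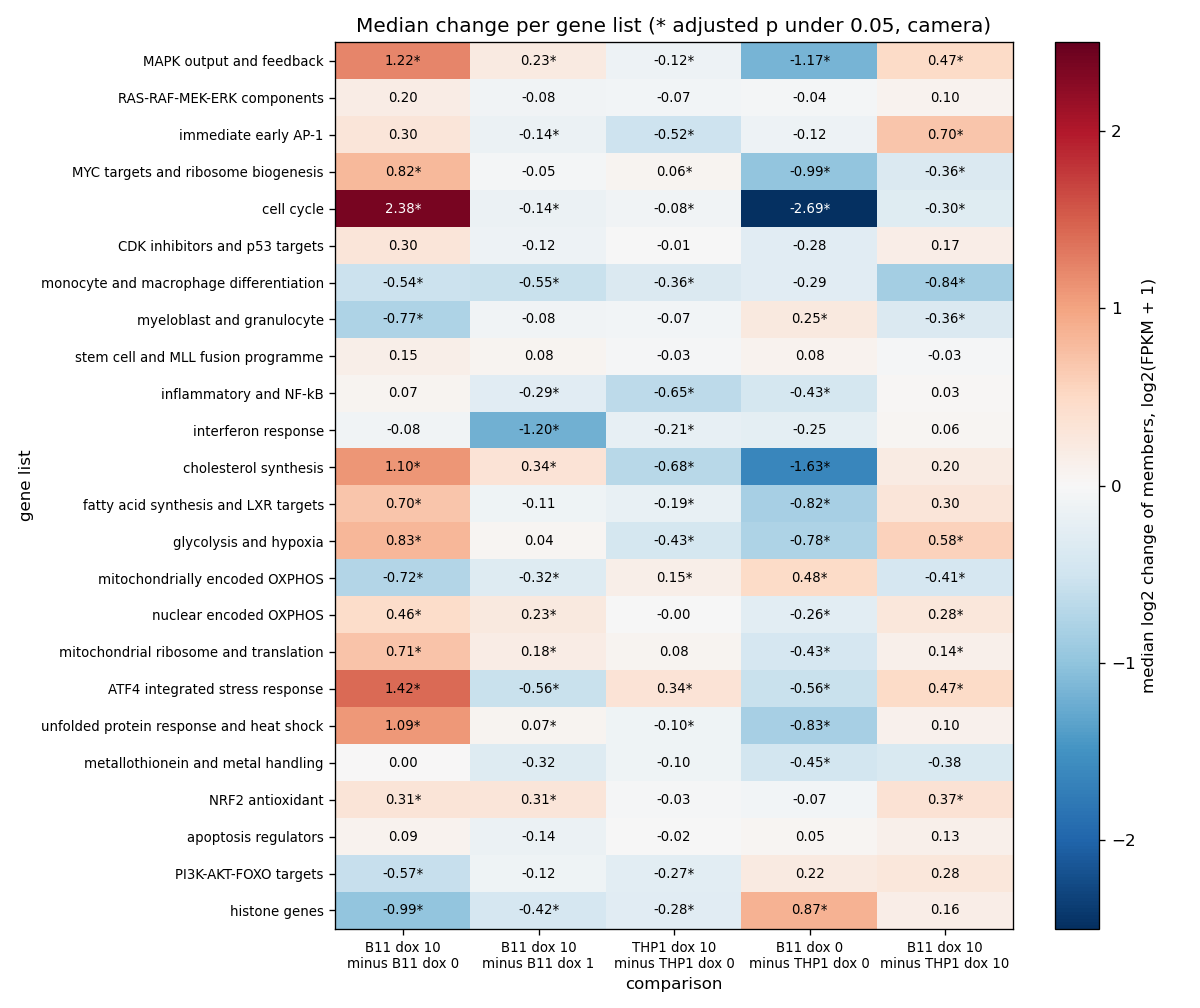
Median log2 change of the members of each gene list in 5 comparisons, with colour and number giving the median and a star marking adjusted p under 0.05 by camera at the preset correlation. The median of cell cycle genes is 2.38 for B11 at 10 against 0 ug/ml and -2.69 for untreated B11 against THP1.

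Of the 179 genes called in THP1 at 10 against 0 ug/ml, 9 were higher and 50 lower in both lines, where independent calls would give 3.66 and 34.5. Another 62 were higher in B11 and lower in THP1 against 34.9 by chance, and 3 were lower in B11 and higher in THP1 against 3.62. Among genes with a mean of at least 5 FPKM, 7 were higher and 48 lower in both lines, against 3.74 and 31.3 by chance. In that set 58 were higher in B11 and lower in THP1 against 39.1, and 2 the other way against 2.99. These chance values take every gene as equally likely to be called, which was not tested, so no excess is read as a shared or opposed response. Across all genes tested, the changes correlated at Pearson r = 0.0181. In B11 the responses to 1 and 10 ug/ml shared 2765 higher and 2328 lower genes, against 748 and 648 by chance, and 58 were called in opposite directions. Pearson r across genes was 0.797, against 0.509 in 20 simulations of unchanged groups with shared controls, and the covariance was 0.572 against 0.0801, a difference of 0.492. The simulations called a mean of 0.25 genes in both, but they held no changed genes, so this count cannot be set beside the shared genes. The 3 shared controls cannot be divided into sets of at least 2, so part of the excess of shared genes over independent calls may come from them.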

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

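The splits of libraries for the 12 counts were planned before the result was seen, and the 4 tests of the explanations weighed here were chosen only after it was seen.

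Interferon genes in B11 changed by a median of -1.20 from 1 to 10 ug/ml. In THP1 the list was called lower at both doses against 0 ug/ml, with medians of -0.196 at 1 and -0.209 at 10 ug/ml, but its median from 1 to 10 ug/ml was 0.045 and the list was called lower in the interaction of 10 against 1 ug/ml (median -1.07). The THP1 median argues against doxycycline itself as the source of the fall from 1 to 10 ug/ml in B11. That holds only if B11 responds to the drug as THP1 does, which was not tested. The interaction uses the same B11 libraries and adds no separate evidence. Whether the 2 B11 libraries at 1 ug/ml with the very high unnamed ID contributed stays open, since the median without both was -1.304 but rested on the 1 library left at that dose. That ID was at 1.95e-37 FPKM or less in every other library, far below the value of 1 fragment, and how its values arose is unclear. Across genes, these libraries, B and C, correlated with each other at Pearson r of 0.9575, and with library A at 0.9528 and 0.9491. The amount of NRAS G12V protein was not analysed here, so a dose effect of the transgene is untested.

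Cholesterol synthesis genes had a median of 1.10 in B11 at 10 against 0 ug/ml and -0.684 in THP1. Scaling of the libraries was weighed as a source of the opposite signs. The medians were 1.18 and -0.670 with TPM and 1.08 and -0.683 with the median of ratios. Mean TPM shifts at 0 and 10 ug/ml were -0.241 and -0.165 log2 in B11 and -0.104 and -0.0919 in THP1. Shifts of this size were too small to turn either sign, so these 2 scalings do not account for the opposite signs. Untreated B11 started from 18.3 FPKM of HMGCS1 against 90.8 in THP1, and whether the starting level sets the direction was not tested.

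Between the lines, 1098 genes were higher and 1078 lower in B11 at all 3 doses, and 352 were called in opposite directions at different doses. RNA of other cell types in B11 was tested as a source. In the 4 lists of other cell types, 0% of the members were higher in B11 at all doses at 5 FPKM or more. Only 5 of 14 T and NK cell, 4 of 11 B cell, 3 of 18 erythroid and megakaryocyte and 4 of 16 epithelial, fibroblast and kidney genes passed the filter. This argues only against a large share of RNA from those 4 types, since a small share could stay below the filter. Genes outside the lists were not counted, among them NCAM1, FCER2 and CLDN7, which are given above as higher in B11 than in THP1. Drift of the clone, the editing and the integrated transgene were not separable with 1 clone.

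Responses differed between the lines for 5230 genes at 10 ug/ml, 4544 at 1 ug/ml and 814 from 1 to 10 ug/ml. The median difference of the responses at 10 ug/ml was 1.59 for MAPK output genes, 2.52 for cell cycle genes, 1.83 for cholesterol synthesis genes, 0.799 for fatty acid synthesis and LXR genes, 1.19 for glycolysis and hypoxia genes, -0.894 for mitochondrially encoded genes and 1.12 for unfolded protein response genes. The highest value among IDs below the filter was 76850 FPKM, in 1 unnamed ID in B11 library B at 1 ug/ml.

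For comparisons of 2 groups the 6 libraries allow 10 splits, too few for a share under 0.05. The number of splits with as many genes as the real one was 1 in B11 at 10 against 0 ug/ml (7520 genes, highest other 2), 1 at 1 against 0 ug/ml (6516, highest other 5) and 1 at 10 against 1 ug/ml (2249, highest other 2). In THP1 it was 1 at 10 against 0 ug/ml (179, highest other 1), 4 at 1 against 0 ug/ml (2, highest other 4) and 1 at 10 against 1 ug/ml (52, highest other 4). Between the lines it was 1 at 0 ug/ml (8269, highest other 3), 1 at 1 ug/ml (5231, highest other 1) and 1 at 10 ug/ml (5691, highest other 2). Every other split mixes the 2 groups, which cancels much of their difference and adds it to the spread within groups. Low counts in those splits were therefore built in and are no separate evidence. For the interactions 100 splits were drawn. The real count was reached by 4 at 10 ug/ml (5230, highest other 5585), 2 at 1 ug/ml (4544, highest other 4556) and 5 for 10 against 1 ug/ml (814, highest other 1230). All other splits as large kept the B11 libraries parted by dose. Of the other splits drawn, 11, 9 and 9 did so, and 3, 1 and 4 of these reached the real count. They still hold the B11 dose effect and regroup only THP1 libraries. The highest count with the B11 libraries mixed was 13, 6 and 9. The shares therefore follow mostly whether the B11 libraries stayed parted. For none of the 3 counts do they decide whether the difference between the lines arose by chance.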

How the results depend on the processing

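Most alternatives were set before the data were examined. The restriction to named protein-coding genes of at least 300 exonic bases and the fit without B11 libraries B and C at 1 ug/ml were chosen after seeing the data. Over 1105 gene results and 20842 alternatives, 20114 gave the same result, passing or not, 704 were weaker, 24 stronger and 0 reversed, and 156 results had at least 1 weaker alternative. For genes and lists alike, a result called in neither fit counted as the same whatever its sign. Many genes were named for a large change or a small p, so a high share of equal results was partly built in. Of 1344 alternatives to the 336 list tests, 1165 gave the same result, called or not, 109 were weaker, 70 stronger and 0 reversed. Lists called numbered 169, and 71 with an estimated correlation, 229 with fry, 170 with the median of ratios and 167 with the block.

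NRAS in B11 from 1 to 10 ug/ml did not hold with a pseudocount of 0.1 (0.232) or 0.5 (0.228), the median of ratios (0.218), TPM (0.225), robust moderation, no trend, the block, only the compared groups or protein-coding genes (0.224 each), without any 1 of the 6 libraries (0.209 to 0.242), or without B11 libraries B and C at 1 ug/ml (0.188). NRAS in B11 from 0 to 1 ug/ml passed without a filter or at a mean of 5 FPKM (0.177 each), with TPM (0.246) and without B11 library B at 0 ug/ml (0.21), and was 0.139 to 0.21 without 1 library. NRAS from 0 to 10 ug/ml stayed at 0.363 to 0.435 without 1 library. The cause was not tested.

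In THP1 from 1 to 10 ug/ml the count of 52 became 31 and 32 with pseudocounts of 0.1 and 0.5, 34 without a filter, 28 without a trend, 18 with the block, 11 with only the compared groups and 13 to 21 without 1 library. The 2 genes of THP1 at 1 against 0 ug/ml became 0 with a pseudocount of 0.5, 23 without a filter, 1 at a mean of 5 FPKM, 1 with the median of ratios, 1 with TPM, 7 without a trend, 0 with the block, 10 with protein-coding genes and 0 to 4 without 1 library. The 179 of THP1 at 10 against 0 ug/ml became 46 with only the compared groups and 67 to 121 without 1 library, lowest without THP1 library B at 0 ug/ml. The cause was not tested.

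Without B11 libraries B and C at 1 ug/ml, which left 1 library at that dose, the count was 4053 in B11 at 1 against 0 ug/ml, 601 at 10 against 1 ug/ml, 2687 between the lines at 1 ug/ml and 230 for the interaction of 10 against 1 ug/ml. Without 1 library the counts were 6543 to 6866 for B11 at 10 against 0 ug/ml, 5534 to 5825 at 1 against 0 ug/ml and 1475 to 1724 at 10 against 1 ug/ml, with 1475 without B11 library C at 10 ug/ml and 1478 without B11 library C at 1 ug/ml. They were 7331 to 7582, 4217 to 4472 and 4771 to 5099 between the lines at 0, 1 and 10 ug/ml, and 4613 to 5028, 3925 to 4281 and 495 to 748 for the interactions at 10, at 1 and of 10 against 1 ug/ml, the lowest, 495, without B11 library C at 1 ug/ml. With a change of at least 1.5-fold, 25 genes went in the same direction in both lines at 10 ug/ml and 3385 at both doses in B11. The cause was not tested.

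With the replicate letter as a block 7422 genes passed in B11 at 10 against 0 ug/ml, 136 in THP1 at 10 against 0 ug/ml and 8203 between the untreated lines. Correlations of residuals between libraries of the same letter in different groups ranged from -0.0705 to 0.0923 over 45 pairs, and 7 of 18 libraries were closest to their own letter, so the letters were not used as pairs.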

Other observations

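Other lists were not called as a whole in B11 at 10 against 0 ug/ml, though members of them passed. Of 38 interferon response genes, 11 fell and 7 rose (7 higher and 13 lower adjusted over the list alone, median -0.08, camera, adjusted p = 0.191), and of 16 metallothionein and metal handling genes, 4 rose and 2 fell (the same adjusted over the list alone, median 0.00, camera, adjusted p = 0.497). FOS, an immediate early gene, changed by 2.07 (SE 0.16) and KLF4 by -1.86 (SE 0.16), and of 16 immediate early genes 10 rose and 4 fell (the same adjusted over the list alone, median 0.30, camera, adjusted p = 0.138). The chemokine CCL5 changed by 3.16 (SE 0.08) and the cytokine TNF by 2.52 (SE 0.21), and of 30 inflammatory genes 7 rose and 7 fell (the same adjusted over the list alone, median 0.07, camera, adjusted p = 0.76). CDKN1A, which encodes the CDK inhibitor p21, changed by 1.41 (SE 0.11), and of 23 CDK inhibitors and p53 targets 11 rose and 5 fell (the same adjusted over the list alone, median 0.30, camera, adjusted p = 0.171). BMF, a promoter of apoptosis, changed by -2.56 (SE 0.18), and of 24 apoptosis regulators 8 rose and 7 fell (the same adjusted over the list alone, median 0.09, camera, adjusted p = 0.789). FLT3, a receptor of early progenitors, changed by -1.37 (SE 0.09), and of 33 stem cell and MLL fusion genes 7 rose and 7 fell (the same adjusted over the list alone, median 0.15, camera, adjusted p = 0.704).

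NKD2 was at 10.4 ± 0.588 FPKM in untreated B11, 27.3 ± 1.80 at 1 ug/ml and 48.9 ± 2.12 at 10 ug/ml, and at 10.4 ± 1.01, 17.8 ± 2.05 and 19.5 ± 1.61 in THP1. CCND1 was at 0.279 ± 0.345, 5.99 ± 1.32 and 17.6 ± 3.14 FPKM in B11 and at 7.73 ± 1.43, 6.10 ± 2.52 and 7.45 ± 0.699 in THP1.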
